A study of Gallus gallus with 6 samples.

How the data were processed

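RNA was measured in 6 libraries made from chicken (Gallus gallus) embryo primary skeletal muscle cells at passage 1, 3 from dividing myoblasts and 3 from differentiated myotubes. Per the labels' protocols, the dividing cells grew in RPMI-1640 with 15% fetal bovine serum, differentiation was induced in RPMI-1640 with 2% horse serum, both media held 2% penicillin and streptomycin, RNA was taken with Trizol, and the libraries followed Illumina's standard preparation. Each library's group was taken from its developmental stage label and its replicate number from its title.

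Per the submitters' processing notes the reads were handled with HISAT and HTSeq. Their versions, the genome build, the annotation version, the strand setting and any filter are not given in the sources used here. Each deposited table held, per the file headers, the read count of every gene as whole numbers and, beside it, the FPKM that the authors computed, which scales the count to gene length and to the total of the library. The FPKM of 66.6% of the values equalled the count divided by the table's length column and by the library's total within 1%, and the others implied a shorter length than that column. The tables had 26591 gene entries, 24881 with an Ensembl identifier and 1710 without one, and 2 further lines per table that named no gene and were left out. A symbol was given for 11074 entries, and 15517 had none. Gene coordinates are as in the deposited tables, whose build is not given in the sources used here. Where strand is not known to have been used, reads of overlapping genes and of antisense partners cannot be told apart. Reads of related genes (the alpha globins HBAA and HBAD, the class I genes BF1 and BFIV21, ribosomal proteins and their pseudogenes) may have been split or lost in counting where their sequences are alike.

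Total counts ran from 21893152 to 27546527 per library. The count test was edgeR's quasi-likelihood test in R 4.3.3 (edgeR 4.0.16) on the counts as deposited, with filterByExpr at its default minimum count of 10 and total of 15, TMM scaling, a model of the 2 groups with no block, two-sided p-values and Benjamini-Hochberg adjustment over the 15959 genes that passed the filter, of which 9646 had a symbol. A gene was called at an adjusted p under 0.05. Log2 changes are myotube minus myoblast. Their errors, given as SE, are the size of the log2 change divided by the square root of the test's F statistic. They approximate a standard error and were not an output of the model itself. The design fixed before the data were examined had assumed FPKM tested with limma unless counts were present; counts were present, so the count test was used and limma on log2(FPKM + 1) became an alternative. The test, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined.

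The lists held 1265 symbols in 34 lists, of which 924 matched a gene in the tables (10 through a synonym) and 341 did not. They covered contraction (sarcomere, excitation and contraction coupling, neuromuscular junction, slow and cardiac isoforms, fast isoforms), muscle regulators, fusion and adhesion, DNA replication, mitosis, cyclin-dependent kinase inhibitors, metabolism (glycolysis and creatine, oxidative phosphorylation, mitochondrially encoded genes, cholesterol and fatty acid synthesis), matrix, signalling (serum and immediate early genes, YAP and TEAD targets, growth factors of the IGF, TGF-beta and BMP families, Notch and Wnt), stress, heat shock, ribosomal proteins, interferon response, ubiquitin and autophagy, cell death, and markers of fibroblasts, smooth muscle, endothelium, leukocytes, erythroid cells, nerve and Schwann cells, adipocytes, cartilage and epithelium. Each list with at least 5 tested members was tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The share of summed FPKM of each list and of the highest genes was compared with an exact permutation test, two-sided, which with 3 against 3 libraries cannot go below 0.1.

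Genes were named by 3 rules: the 12 largest increases and the 12 largest decreases among called genes with a symbol, a mean FPKM of at least 10 and no overlap between the groups; in each list up to 4 called members with the largest change and a mean FPKM of at least 2; and a fixed set of muscle, cell cycle and reference genes whatever their result. MYMK had no entry of that name but was analysed as TMEM8C. CKM, MYH1B, ACTA1, ACTC1, TNNT2, MKI67, CDKN1C, COL1A1 and ACTA2 of that set had no entry of that name in the tables and IGF1 did not pass the filter, so these were not analysed here.

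The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, limma on FPKM with other pseudocounts, filters, scalings, weights and a test against 1.5-fold, a stricter threshold, leaving out each library in turn, a replicate block, camera with other settings and fry. The count test, camera, limma and DESeq2, but not the other steps, were run on simulated counts for the same 15959 genes and libraries. There the count test called 75% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 0 in the wrong direction, and called 6 of 15719 unchanged genes. On the same counts limma on log2(CPM + 1) called 96% and DESeq2 99% of the genes changed 4-fold, with 10 and 40 unchanged genes called. The simulated raised list was called, and of 30 unchanged lists 0 were called by camera. Of the 15959 simulated genes 15719 were unchanged, whereas 9436 genes were called in the data, so these rates may not carry over. The simulated genes were drawn independently of each other. This did not test camera on lists whose members are correlated, such as the mitosis list with an estimated correlation of 0.93.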

Results

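RNA was sequenced from primary skeletal muscle cells of chicken embryos in 2 states, dividing myoblasts and differentiated myotubes, with 3 libraries of each. Myoblasts are the single precursor cells of skeletal muscle, which on serum withdrawal can leave the cell cycle and fuse into myotubes with many nuclei. The kind and the amount of serum differed between the groups together with the state of the cells, 15% fetal bovine serum for myoblasts and 2% horse serum for myotubes. Total counts were 24584188, 23164541 and 27546527 in myoblast replicates 1 to 3 and 23519295, 22887248 and 21893152 in myotube replicates 1 to 3. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The series asks which genes differ in expression between the 2 states.

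In the myotube libraries, genes of cell division were lower, and many genes of the extracellular matrix and the ribosome were higher, while most of the contractile genes that passed the test were lower. CDK1, the kinase that drives entry into mitosis, went from 136 ± 42.7 FPKM in myoblasts to 24.6 ± 1.43 FPKM in myotubes (mean ± SD, n = 3 each), a log2 change of -2.41 ± 0.21 (SE). LUM, which encodes the matrix proteoglycan lumican, went from 25.1 ± 6.10 to 286 ± 40.2 FPKM, an 11.9-fold rise, and PHGDH, the first enzyme of serine synthesis, from 70.8 ± 21.8 to 1476 ± 120 FPKM, a 21.6-fold rise. DES, which encodes the muscle intermediate filament desmin, went from 811 ± 407 to 142 ± 7.98 FPKM, a log2 change of -2.47 ± 0.32. All 4 passed the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p from 3.78e-06 for LUM to 0.000289 for DES.

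Of the 15959 genes tested, 4785 rose and 4651 fell in myotubes and 6523 had no call (edgeR quasi-likelihood, Benjamini-Hochberg). At least 2-fold changes made up 2102 of the rises and 1878 of the falls, against 1208 and 1083 with limma on log2(FPKM + 1) and 633 and 517 with limma and a pseudocount of 5. The groups did not overlap in 98.8% of the called genes and in 67.2% of all tested genes, where chance gives 10%. The median log2 change of all tested genes was 0.0003, and 50.7% of the calls were rises. Over the genes tested in both ways the median was 0.01 with edgeR on counts, -0.03 with limma on log2(FPKM + 1) and -0.13 with limma on TPM, and 47.2% and 39.2% of the calls of these limma fits were rises.

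The largest rise by the named-gene rule was in OSTN. This gene, which encodes the muscle and bone secreted peptide osteocrin, went from 0.419 ± 0.0968 to 40.8 ± 6.12 FPKM (n = 3 each, log2 change 6.64 ± 0.22, chromosome 9, 13761297 to 13772476). SPON2 rose 63.2-fold, SFRP2, a secreted Wnt antagonist, 54.1-fold, DPT 44.9-fold, SMOC2 31.9-fold, Fgf16 27.6-fold, COL8A2 23.1-fold, GLT8D2 21.6-fold and CLEC3B 20.2-fold. CHAC1, which degrades glutathione, rose 23.1-fold and PTGS2, the inducible cyclooxygenase, rose 21.5-fold, from 8.48 ± 1.49 to 176 ± 23.4 FPKM. The largest falls by the rule, after the alpha globin HBAA, were in CPM (carboxypeptidase M, log2 change -5.31 ± 0.17, from 90.3 ± 17.1 to 2.19 ± 0.323 FPKM), the collagenase MMP13 (-4.35 ± 0.30), the muscle LIM protein CSRP3 (-4.07 ± 0.34), ADAMDEC1 (-3.82 ± 0.18), the endothelial lipase LIPG (-3.33 ± 0.19) and CACNG4 (-3.31 ± 0.38). LIF, LMCD1, MYF5, KIF11 and TRAIP followed, at -3.02, -3.02, -2.93, -2.86 and -2.83. Adjusted p in these genes was at most 0.000161 (edgeR quasi-likelihood, Benjamini-Hochberg). HBAA had 1054 counts over the myoblast libraries and 1 over the myotube libraries, a ratio of 920 with a 95% counting interval of 165 to 36381 that covers counting error alone. Myoblast replicate 3 held 696 of these counts, and the log2 change of HBAA, -9.37 ± 1.08, was -8.48 without that library and -11.34 without myotube replicate 1.

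Cell division genes fell together. Of 58 mitosis genes tested, 57 fell and 1 had no call, and 57 fell when adjusted over the list alone, with a median log2 change of -2.22 (camera, Benjamini-Hochberg adjusted p = 1.82e-24; adjusted p = 0.516 with an estimated correlation). DIAPH3, NCAPG2, KIF11 and CEP55 had the largest falls with a mean FPKM of at least 2, from -3.04 ± 0.26 to -2.73 ± 0.25, and TOP2A, the topoisomerase of dividing cells, went from 67.5 ± 22.3 to 12.1 ± 0.814 FPKM (-2.41 ± 0.22, n = 3 each). Of 51 DNA replication genes, 43 fell, 3 rose and 5 had no call, and 45 fell and 3 rose when adjusted over the list alone (median -1.57, camera, Benjamini-Hochberg adjusted p = 1.91e-14; adjusted p = 0.516 with an estimated correlation). TK1 and RRM2, which supply nucleotides for DNA synthesis, each changed by -2.79, SLBP by -2.75, EXO1 by -2.70 and the polymerase clamp PCNA by -1.21 ± 0.18. Myoblast replicate 3 had less of both groups than the other myoblast libraries, by -0.83 for the mitosis median and -0.66 for the replication median on the log2 scale. Without it 57 mitosis and 46 replication genes fell.

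Among 21 cyclin-dependent kinase inhibitors and related genes, 7 rose, 6 fell and 8 had no call, the same numbers when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.436). CDKN1A, the p21 inhibitor, went from 33.5 ± 7.59 to 111 ± 15.2 FPKM (log2 change 1.78 ± 0.18, n = 3 each), CDKN2A rose 34.1-fold from 0.348 ± 0.134 to 11.3 ± 1.84 FPKM (chromosome Z, 78627025 to 78636973), and CCNG1 rose 2.91-fold. RBL1 fell (-1.62 ± 0.17), as did cyclin D1, CCND1 (-0.84 ± 0.11), while CDKN1B was at -0.43 ± 0.19 with no call (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0884, and 0.0457 without myoblast replicate 2). Without myoblast replicate 3 CDKN1B was at -0.14. The inhibitor CDKN2C, named after its value was seen, fell (-0.87 ± 0.32, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0431). The median of the list was -0.25, while its mean, 0.26, and its test were above 0.

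**Figure D1:**
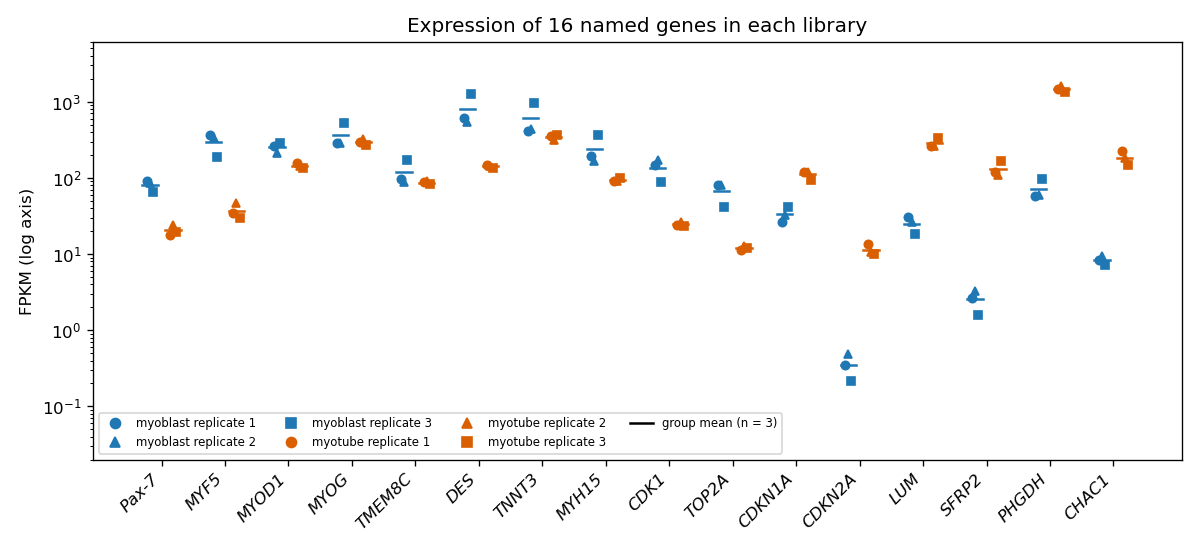
FPKM of 16 named genes in each of the 6 libraries on a log axis, with myoblast libraries in blue, myotube libraries in orange, one marker shape per replicate number and a bar at each group mean (n = 3). CDK1 lies at 136 FPKM on average in myoblasts and 24.6 FPKM in myotubes, PHGDH at 70.8 and 1476 FPKM, and the myoblast values of MYOG, TNNT3 and DES are spread by the higher replicate 3.

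Regulators of the muscle lineage were mostly lower in myotubes. Of 32 tested, 20 fell, 2 rose and 10 had no call. Adjusted over the list alone, the counts were the same (median -0.54, camera, Benjamini-Hochberg adjusted p = 8.96e-05; adjusted p = 0.516 with an estimated correlation). The myoblast factor MYF5 (chromosome 1, 40002758 to 40003972) went from 294 ± 94.7 to 37.0 ± 8.65 FPKM (-2.93 ± 0.26, n = 3 each), Pax-7, a marker of muscle stem cells, from 80.0 ± 14.1 to 20.5 ± 3.39 (-1.91 ± 0.15), and Id1, an inhibitor of myogenic factors, from 196 ± 16.2 to 28.7 ± 4.12 (-2.71 ± 0.13). MYF6 fell (-1.94 ± 0.20), as did PAX3, from 1.42 ± 0.233 to 0.0959 ± 0.0215 FPKM, and MYOD1, from 254 ± 37.2 to 145 ± 11.2 FPKM (-0.75 ± 0.13). MSTN, the growth inhibitor myostatin, rose 2.09-fold. MYOG, the factor that drives differentiation (chromosome 26, 968610 to 972124), was at 367 ± 138 and 300 ± 27.0 FPKM, a log2 change of -0.24 ± 0.24 with no call (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.408), and at 0.14 without myoblast replicate 3, where it stood at 526 FPKM against 287 FPKM in each of the others. MEF2C was at -0.86 ± 0.32 with an adjusted p of 0.0473 by edgeR quasi-likelihood and Benjamini-Hochberg, and its call was lost without myotube replicate 1, 2 or 3 (0.123, 0.129 and 0.101). Without myoblast replicate 3 it was at -0.30. Id3 was at 0.18 ± 0.11 with no call.

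Among sarcomere genes, too, more fell than rose. Of the list's 79 symbols 52 had an entry, and ACTA1, ACTC1 and TNNT2 were among those without one. Of 51 sarcomere genes tested, 30 fell, 2 rose and 19 had no call. When adjusted over the list alone, the counts did not differ, with a median of -0.92 (camera, Benjamini-Hochberg adjusted p = 3.55e-05, or 0.622 with an estimated correlation). Fry made no call for the list (Benjamini-Hochberg adjusted p = 0.0672). Besides DES and CSRP3, MYBPH (-2.75 ± 0.37), the myosin chaperone UNC45B (-2.50 ± 0.30) and MYH15, a myosin heavy chain (242 ± 107 to 94.4 ± 5.55 FPKM, -1.31 ± 0.27, n = 3 each), fell, while MYBPC1 rose (2.74 ± 0.55). Without myoblast replicate 3 MYBPC1 was at 3.94, MYBPH at -2.14 and MYH15 at -0.87. The fast troponin T gene TNNT3 was at 604 ± 314 and 342 ± 28.4 FPKM with no call (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0619). It was called lower without myoblast replicate 1, 2 or 3, with adjusted p of 0.0252, 0.0323 and 0.0417 by edgeR quasi-likelihood and Benjamini-Hochberg, and its log2 change without replicate 3 was -0.23. The list held 1.66 ± 0.574% of summed FPKM in myoblasts and 0.906 ± 0.0169% in myotubes (exact permutation p = 0.1). Myoblast replicate 3 had the most, 2.32% against 1.37% and 1.29% in replicates 1 and 2, and its sarcomere median lay 0.95 above their mean on the log2 scale, where its leukocyte marker median lay 1.00 and its epithelial marker median 0.99 above. Without it 30 sarcomere genes fell and the median was -0.51.

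Slow and cardiac isoforms followed the sarcomere list, with which they share members, with 9 of 16 lower, 2 higher and 5 without a call. These counts were the same when adjusted over the list alone (median -0.74, camera, Benjamini-Hochberg adjusted p = 0.0173, or 0.622 with an estimated correlation). Fry made no call for these isoforms (Benjamini-Hochberg adjusted p = 0.0524). MYL4 fell by 2.36 and CAV3 by 2.60 on the log2 scale. Of the 27 fast isoform symbols 10 had an entry, of which 2 rose, 2 fell and 6 had no call, also when adjusted over the list alone. The median was -0.55, the mean -0.06 and the test direction up (camera, Benjamini-Hochberg adjusted p = 0.874). PVALB (2.81 ± 0.28) and ENO3 (2.78 ± 0.20) rose, and TNNI2 fell (-0.92 ± 0.25, or -0.51 without myoblast replicate 3). Of 33 genes of excitation and contraction coupling, 16 fell, 6 rose and 11 had no call. The same counts resulted when adjusted over the list alone, with no call for the list (median -0.62, camera, Benjamini-Hochberg adjusted p = 0.294); SRL fell (-2.43 ± 0.31) and SLC8A1 rose (2.42 ± 0.15). Of 26 genes of the neuromuscular junction, 14 fell, 4 rose and 8 had no call. Adjusted over the list alone, the counts were the same (median -0.61, camera, Benjamini-Hochberg adjusted p = 0.0106; adjusted p = 0.622 with an estimated correlation). ERBB4, AGRN, DTNA and LAMA2 fell, from -2.15 ± 0.43 to -1.67 ± 0.21, and ERBB4 was at -1.49 without myoblast replicate 3. In myoblast replicate 3 the medians of these lists lay above those of the other myoblast libraries, by 0.87 for slow, 1.17 for fast isoforms, 0.69 for coupling and 0.54 for the junction. Without it 9 slow and cardiac genes and 14 junction genes fell. With each gene centred on its mean over the 6 libraries, fast isoform medians were -0.15 and -0.19 in myoblast replicates 1 and 2. In myotube replicates 1 to 3 they were -0.15, -0.22 and -0.19. Coupling medians in the same libraries were 0.01 and -0.002 against -0.30, -0.31 and -0.16.

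Of 28 genes of fusion and adhesion, 10 rose, 6 fell and 12 had no call. When adjusted over the list alone, the counts did not differ, with no call for the list (median 0.08, which turned to -0.06 on TPM; camera, Benjamini-Hochberg adjusted p = 0.288). CDH11 (2.45 ± 0.10) and the membrane repair gene DYSF (1.36 ± 0.11) rose and NPNT fell (-1.40 ± 0.10). ITGA7 fell (-1.29 ± 0.41), but lost its call without myotube replicate 1 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0891 and 0.0711) and was at -0.61 without myoblast replicate 3. TMEM8C, the fusion gene myomaker, was at 118 ± 45.6 and 86.8 ± 4.58 FPKM (n = 3 each) with no call, at a log2 change of -0.40 ± 0.24 and an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.187. Without myoblast replicate 3 TMEM8C was at -0.01.

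More matrix genes and fibroblast markers rose than fell. Of 56 matrix genes, 33 rose, 13 fell and 10 had no call. These counts were the same when adjusted over the list alone (median 0.64, camera, Benjamini-Hochberg adjusted p = 0.00323; adjusted p = 0.622 with an estimated correlation). The elastic fibre genes FBLN5, MFAP2 and FBLN1 rose 22.4-fold, 15.9-fold and 9.53-fold. Of 29 fibroblast markers, 20 rose, 5 fell and 4 had no call. The same counts resulted when adjusted over the list alone (median 0.94, camera, Benjamini-Hochberg adjusted p = 1.40e-06; adjusted p = 0.516 with an estimated correlation). SFRP2, DPT, CLEC3B and LUM led it. The fibroblast list held 0.755 ± 0.0951% of summed FPKM in myoblasts and 0.783 ± 0.0396% in myotubes (n = 3 each, exact permutation p = 0.8), a difference of 0.027 percentage points that was -0.028 without myoblast replicate 3. Without that library 33 matrix genes and 20 fibroblast markers rose.

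Markers of other cell types moved in both directions. Of 8 erythroid markers, 6 fell and 2 had no call, also when adjusted over the list alone (median -2.06, or -1.29 by limma on FPKM; camera, Benjamini-Hochberg adjusted p = 0.0445; adjusted p = 0.516 with an estimated correlation); the list's adjusted p was 0.0502 without myoblast replicate 3 and 0.0522 without myotube replicate 1. HBAD had 319 counts in myoblasts and 1 in myotubes, a ratio of 279 (95% counting interval 49.6 to 11035). Its log2 change, -7.65 ± 1.17, was -6.56 without myoblast replicate 3 and -9.61 without myotube replicate 2. HBE (-2.91 ± 0.54, or -4.05 without myotube replicate 3) and GYPC (-0.61 ± 0.11) fell. Of 9 epithelial markers, 6 fell and 3 had no call, also when adjusted over the list alone (median -1.69, camera, Benjamini-Hochberg adjusted p = 0.0445, or 0.622 with an estimated correlation). The list's adjusted p by camera was 0.0579, 0.0504 and 0.0599 without myoblast replicate 3, myotube replicate 1 and myotube replicate 3. By limma on log2(FPKM + 1) 3 epithelial markers were called lower. TP63, CDH1 and KRT19 fell (-2.28 ± 0.30, -1.69 ± 0.31 and -1.39 ± 0.33), KRT19 being at -0.90 without myoblast replicate 3. Of 10 nerve and Schwann cell markers, 7 fell, 1 rose and 2 had no call, also when adjusted over the list alone (median -1.29, camera, Benjamini-Hochberg adjusted p = 0.0207, and 0.0502 without myoblast replicate 3; adjusted p = 0.516 with an estimated correlation). ELAVL4, SYT1 and PMP22 fell (-2.59 ± 0.28, -1.68 ± 0.17 and -1.28 ± 0.15) and NEFL rose (2.83 ± 0.23).

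Camera made no call for the lists of leukocyte, endothelial, smooth muscle, adipocyte and cartilage markers, while fry called the last 4 (Benjamini-Hochberg adjusted p = 0.00451, 0.0140, 0.00338 and 0.00312). Fry asks whether a list moves on its own. With 59.1% of all tested genes called, a fry call does not set a list apart from other genes. Of 21 leukocyte markers 9 rose, 1 fell and 11 had no call, and 7 rose and 1 fell when adjusted over the list alone (median 0.57, camera, Benjamini-Hochberg adjusted p = 0.231, and 1.14e-05 without myoblast replicate 3). MPEG1, LY86 and CTSS rose (1.97 ± 0.38, 1.89 ± 0.40 and 1.26 ± 0.26). Without myoblast replicate 3 the values were 2.67 for MPEG1 and 2.57 for LY86. RAC2 (1.46 ± 0.53, or 2.60 without myoblast replicate 3) lost its call without any one library other than myoblast replicate 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.0735 to 0.106). Of 11 endothelial markers 3 rose, 5 fell and 3 had no call. Adjusted over the list alone, the counts were the same (median -1.30, or -0.40 by limma on FPKM; camera, Benjamini-Hochberg adjusted p = 0.231). The list's share of summed FPKM went the other way, from 0.00367 ± 0.000275% to 0.00576 ± 0.000360% (n = 3 each, exact permutation p = 0.1). CLDN5 (2.30 ± 0.13), the member with the highest mean FPKM, went from 5.14 ± 0.367 to 24.4 ± 2.91 FPKM. EGFL7 (1.58 ± 0.21) was also higher and FLT1 (-1.94 ± 0.19) lower. FLT4, KDR, TIE1 and SOX18, named after their values were seen, fell by -3.64 to -2.51, at mean FPKM of 0.139 to 1.36. LMO2 (0.45 ± 0.14) lost its call without myoblast replicate 1 or myotube replicate 2 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0745, 0.0665 and 0.0799). Of 17 smooth muscle and pericyte markers 7 rose, 7 fell and 3 had no call, and 9 rose and 8 fell when adjusted over the list alone (median 0.43, camera, Benjamini-Hochberg adjusted p = 0.288). TAGLN went from 222 ± 49.9 to 1179 ± 193 FPKM (n = 3 each), and MYLK (2.67 ± 0.10) and LMOD1 (2.23 ± 0.11) rose. DES, which is also on this list, fell (-2.47 ± 0.32). Of 10 adipocyte markers 5 rose, 2 fell and 3 had no call. When adjusted over the list alone, the counts did not differ (median 0.41, or 0.18 by limma on FPKM; camera, Benjamini-Hochberg adjusted p = 0.444), with PPARG, Lpin1 and AGPAT2 higher (1.84 ± 0.11, 0.88 ± 0.12 and 0.84 ± 0.14) and SCD lower (-1.15 ± 0.13). Of 8 cartilage markers 3 rose, 4 fell and 1 had no call. These counts were the same when adjusted over the list alone (median -0.28, mean 0.18, camera direction up, Benjamini-Hochberg adjusted p = 0.468), and the median was 0.01 by limma on FPKM. CHAD and COMP rose (4.27 ± 0.19 and 2.58 ± 0.17) and CNMD and SOX9 fell (-1.70 ± 0.19 and -0.90 ± 0.19).

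**Figure D2:**
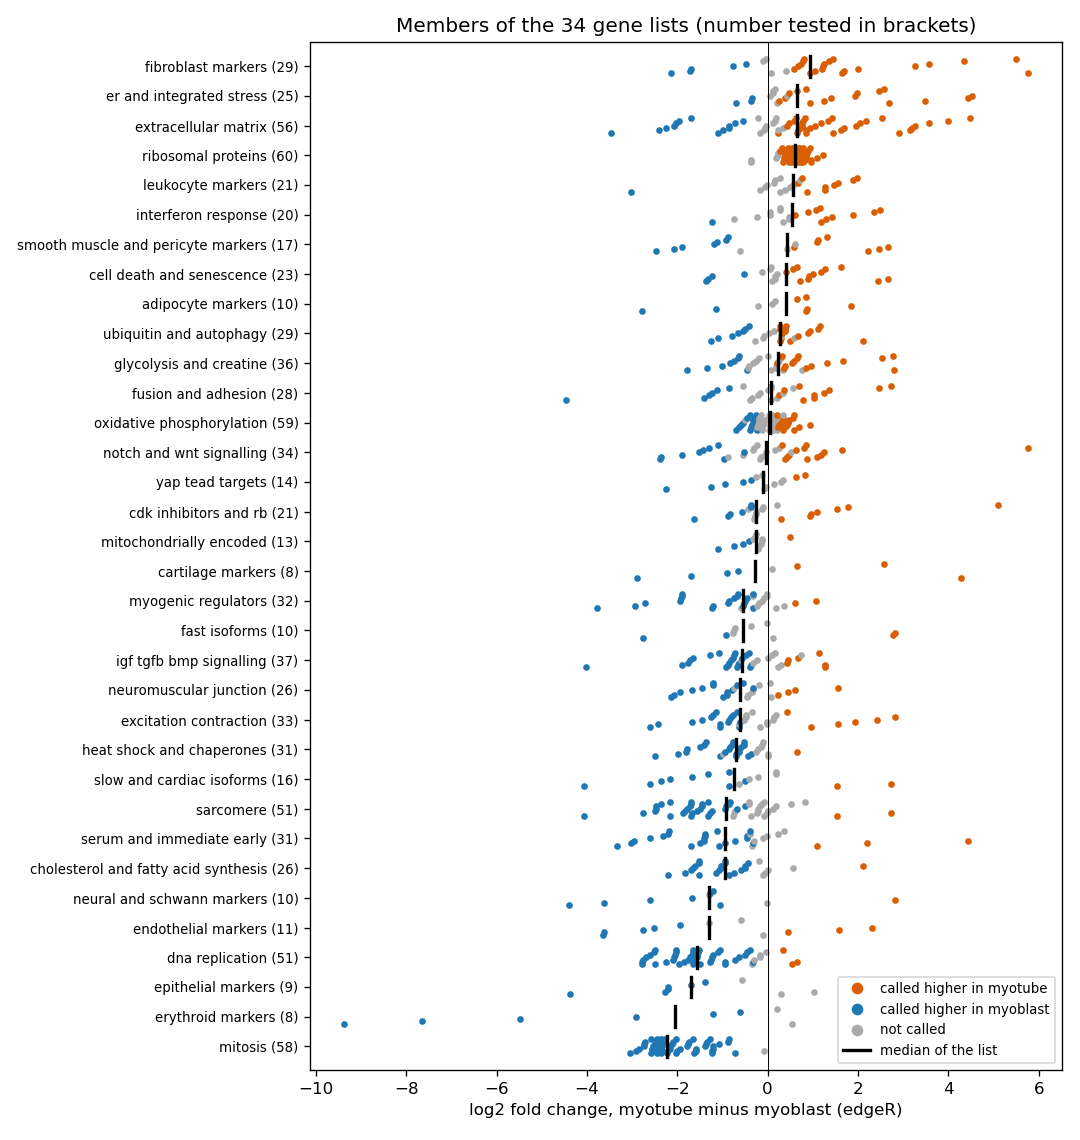
Log2 change, myotube minus myoblast, of each tested member of the 34 gene lists, with rises in orange, falls in blue, genes without a call in grey, a black bar at each median and the number tested in brackets. The mitosis list has the lowest median, -2.22, and the fibroblast list the highest, 0.94.

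Of 25 genes of endoplasmic reticulum and integrated stress, 16 rose, 3 fell and 6 had no call. The same counts resulted when adjusted over the list alone (median 0.65, camera, Benjamini-Hochberg adjusted p = 1.08e-09; adjusted p = 0.516 with an estimated correlation). Besides PHGDH and CHAC1, the cystine carrier SLC7A11 rose 11.2-fold and the amino acid carrier SLC7A5 6.44-fold. Heat shock genes and chaperones fell in 22 of 31 cases, with 1 rise and 8 without a call. Adjusted over the list alone, the counts were the same (median -0.70, camera, Benjamini-Hochberg adjusted p = 4.41e-06; adjusted p = 0.516 with an estimated correlation). The small heat shock genes HSPB8, HSPB2 and HSPB1, which muscle also expresses, changed by -1.98 ± 0.30, -1.80 ± 0.41 and -1.77 ± 0.20, HSPB2 being at -1.18 without myoblast replicate 3. Of 23 genes of cell death and senescence, 12 rose, 4 fell and 7 had no call. When adjusted over the list alone, the counts did not differ (median 0.42, camera, Benjamini-Hochberg adjusted p = 0.0233, and 0.0589 without myoblast replicate 3; adjusted p = 0.516 with an estimated correlation). The death receptor FAS rose (2.67 ± 0.12), as did the p53 targets TP53INP1 (2.44 ± 0.11) and TP53I3 (1.63 ± 0.23). BCL2, which opposes cell death, fell (-1.36 ± 0.11), while its relative BCL2L1, named after its value was seen, rose (0.93 ± 0.09).

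Of 31 serum and immediate early genes, 21 fell, 3 rose and 7 had no call. These counts were the same when adjusted over the list alone (median -0.94, camera, Benjamini-Hochberg adjusted p = 4.23e-05; adjusted p = 0.516 with an estimated correlation). NR4A3 and FOS fell (-3.02 ± 0.24 and -2.32 ± 0.18), and PLAU rose beside PTGS2 (2.21 ± 0.21). Cholesterol and fatty acid synthesis genes fell in 20 of 26 cases, 1 rose and 5 had no call, against 21 falls and 1 rise when adjusted over the list alone (median -0.95, camera, Benjamini-Hochberg adjusted p = 1.08e-09; adjusted p = 0.181 with an estimated correlation). INSIG1, NSDHL and LSS changed by -2.21 ± 0.10, -1.83 ± 0.10 and -1.69 ± 0.07, and the NADPH-producing enzyme ME1 rose (2.11 ± 0.18). Of 37 genes of IGF, TGF-beta and BMP signalling, 22 fell, 6 rose and 9 had no call, against 23 and 7 when adjusted over the list alone (median -0.57, camera, Benjamini-Hochberg adjusted p = 0.00896; adjusted p = 0.516 with an estimated correlation). TGFBI, IGFBP2 and SMAD9 fell (-1.90 ± 0.13, -1.77 ± 0.19 and -1.64 ± 0.16), while CHRD and IGF2 rose (1.28 ± 0.20 and 1.27 ± 0.16).

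Notch and Wnt genes had no call as a list with camera, with 13 of 34 higher, 9 lower and 12 without a call. The same counts resulted when adjusted over the list alone (median -0.04, mean 0.01, camera direction down, Benjamini-Hochberg adjusted p = 0.973). SFRP1 rose (1.65 ± 0.19), and the Notch target HEYL (-1.90 ± 0.24) and WNT5B (-1.53 ± 0.16) fell. Of 14 YAP and TEAD targets 2 rose, 5 fell and 7 had no call. Adjusted over the list alone, the counts were the same (median -0.10, camera, Benjamini-Hochberg adjusted p = 0.294). ABLIM1, PTPN14 and ANKRD1 fell (-2.26 ± 0.18, -1.26 ± 0.10 and -0.95 ± 0.19), and CTGF rose (0.82 ± 0.11).

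Ribosomal protein genes rose in 55 of 60 cases with 5 without a call, and 57 rose and 1 fell when adjusted over the list alone (median 0.61, camera, Benjamini-Hochberg adjusted p = 4.68e-09; adjusted p = 0.516 with an estimated correlation). RPS15, RPL15 and RPS12 were among those that rose, by 1.23 ± 0.12, 0.96 ± 0.08 and 0.95 ± 0.10. Together the list held 10.1 ± 0.449% of summed FPKM in myoblasts and 14.1 ± 0.863% in myotubes (n = 3 each, exact permutation p = 0.1), and under quantile normalization 22 members rose. Of 20 interferon response and antigen presentation genes, 10 rose, 1 fell and 9 had no call, against 12 and 1 when adjusted over the list alone (median 0.54, camera, Benjamini-Hochberg adjusted p = 0.000701; adjusted p = 0.550 with an estimated correlation). The class I genes BF1 and BFIV21 rose (2.49 ± 0.12 and 2.36 ± 0.12), though such similar genes can share reads, as did B2M (1.89 ± 0.13) and TAP1 (1.43 ± 0.22). Of 29 ubiquitin and autophagy genes 15 rose, 7 fell and 7 had no call. When adjusted over the list alone, the counts did not differ (median 0.28, camera, Benjamini-Hochberg adjusted p = 0.273), with ASB9, BNIP3 and CTSB higher (2.10 ± 0.26, 1.16 ± 0.10 and 1.12 ± 0.12) and ASB2 lower (-1.26 ± 0.30, or -0.81 without myoblast replicate 3).

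Camera made no call for the lists of energy genes. Of 36 genes of glycolysis and creatine metabolism 15 rose, 8 fell and 13 had no call, against 16 and 8 when adjusted over the list alone (median 0.22, camera, Benjamini-Hochberg adjusted p = 0.315); PFKFB1 and AK1 rose (2.53 ± 0.20 and 1.68 ± 0.20) and PGM5 fell (-1.78 ± 0.30). Of 59 genes of oxidative phosphorylation 16 rose, 14 fell and 29 had no call, against 16 and 13 when adjusted over the list alone (median 0.06, which turned to -0.10 on TPM, mean 0.02, camera direction down, Benjamini-Hochberg adjusted p = 0.874). NDUFA1 and NDUFS5 rose (0.93 ± 0.13 and 0.70 ± 0.09), and FH and CYCS fell (-0.70 ± 0.07 and -0.64 ± 0.09). Of 13 mitochondrially encoded genes 4 fell, 1 rose and 8 had no call, against 3 and 1 when adjusted over the list alone (median -0.26, camera, Benjamini-Hochberg adjusted p = 0.231). MT-ND2 and ND5 fell (-1.11 ± 0.15 and -0.75 ± 0.15), MT-CO2 fell (-0.54 ± 0.14) with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0514 without myotube replicate 2, and MT-ND3 rose (0.50 ± 0.10) but was at -0.011 under quantile normalization. Of the reference genes, ACTB fell (-0.74 ± 0.10) and GAPDH was at 0.20 ± 0.08 with an adjusted p of 0.0475 by edgeR quasi-likelihood and Benjamini-Hochberg, which ranged from 0.0844 to 0.137 without any one library other than myoblast replicate 3.

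**Figure D3:**
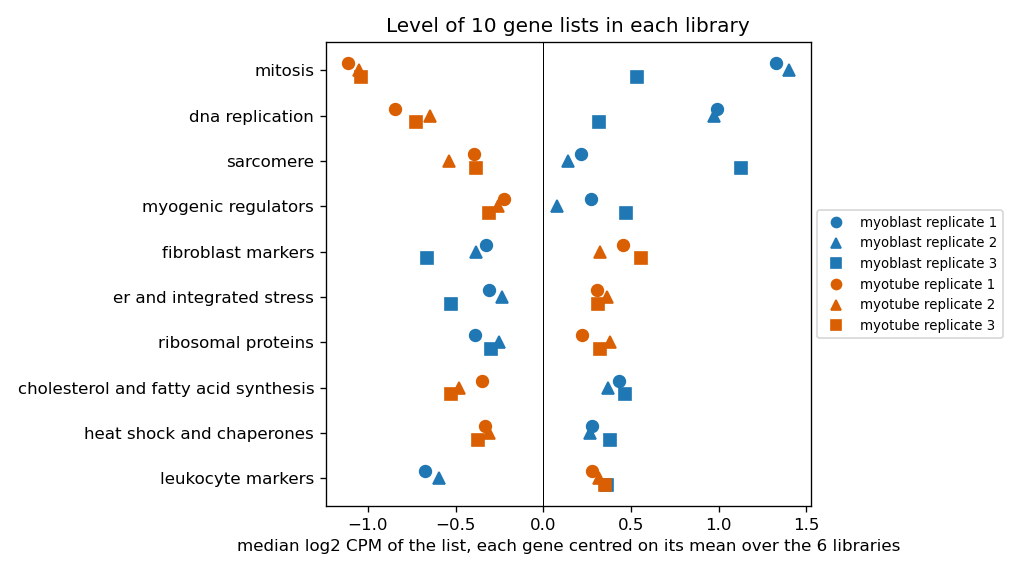
Median log2 CPM of 10 gene lists in each library, each gene centred on its mean over the 6 libraries, with myoblast libraries in blue and myotube libraries in orange. The mitosis medians lie at 1.33, 1.40 and 0.53 in myoblast replicates 1 to 3 and between -1.11 and -1.04 in myotubes, and the sarcomere median of myoblast replicate 3 is 1.13.

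Replicates resembled each other more than the other group. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.985 to 0.995 within myoblasts, 0.992 to 0.995 within myotubes and 0.922 to 0.935 between the groups. The chi-square per gene between 2 libraries' counts was 10.6 to 59.9 within myoblasts and 7.84 to 17.7 within myotubes, far above sampling noise, so no library was counted as a copy of another. The first principal component held 84.9% of the variance and separated the groups, and the second, 7.53%, placed myoblast replicate 3 at -27.8, apart from the other myoblast libraries, which were above 0. The 100 genes with the highest FPKM held 28.7 ± 0.691% of summed FPKM in myoblasts and 32.6 ± 0.118% in myotubes (n = 3 each, exact permutation p = 0.1, the smallest possible), the 50 highest 20.4 ± 0.822% and 21.8 ± 0.137% (exact permutation p = 0.1), and the 10 highest 8.75 ± 0.718% and 7.61 ± 0.547% (exact permutation p = 0.2). Without mitochondrially encoded genes the 10 highest held 6.60 ± 0.324% and 6.66 ± 0.122% (exact permutation p = 0.8), and the 50 highest 17.0 ± 0.373% and 20.4 ± 0.366% (exact permutation p = 0.1). Mitochondrially encoded genes took 4.39 ± 0.566% of the counts in myoblasts and 3.49 ± 0.607% in myotubes (exact permutation p = 0.2).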

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

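The limma fit on log2(FPKM + 1) that other FPKM settings change, DESeq2 size factors in camera, list member counts under other fits, and named genes under other fits were alternatives chosen after seeing the data. Where a value changed, the cause was not tested unless stated. Main counts were 4785 genes higher in myotubes and 4651 genes higher in myoblasts; they were 4627 and 4610 with DESeq2 and 3903 and 4365 with limma on log2(FPKM + 1). That limma fit gave 3014 and 3537 at a mean FPKM of at least 5, 1205 and 1010 against a change of 1.5-fold, and 5072 and 5586 with array weights. Genes at least 2-fold higher in myotubes, 2102, and genes at least 2-fold higher in myoblasts, 1878, were 2314 and 2138 with edgeR without a filter and 1208 and 1083 with limma on log2(FPKM + 1). In that limma fit the added 1 shrinks low genes, but the test, the filter and the measure also differ from the main fit. Against that limma fit, its other settings gave 1519 and 1381 with a pseudocount of 0.1, 633 and 517 with one of 5, 1230 and 1123 without a filter, 878 and 750 at FPKM 5, 1255 and 1036 with median-ratio scaling, 1206 and 1091 with quantile normalization, 1206 and 1083 without trend, 1207 and 1083 robust, 1232 and 1110 with array weights, 1093 and 895 against 1.5-fold, and 1137 and 1388 on TPM. Deviations of same-numbered libraries correlated at 0.04, 0.03 and -0.05, and not every library correlated best with its own number. This gave no sign that the replicate numbers pair the samples, but 3 libraries per group cannot exclude it. With the replicate block edgeR called 4579 and 4381 genes, limma 1210 and 1084 at least 2-fold, and camera changed no list call. With an estimated correlation the 19 called lists lost their call, at an adjusted p (camera, Benjamini-Hochberg) of 0.622 for sarcomere, slow and cardiac isoforms, neuromuscular junction, extracellular matrix and epithelial markers, 0.550 for interferon response, 0.181 for cholesterol and fatty acid synthesis, and 0.516 for the other 12. Under fry, which asks whether a list moves on its own, sarcomere (0.0672) and slow and cardiac isoforms (0.0524) lost the call. Fry calls were gained by fusion and adhesion (0.00380), cyclin-dependent kinase inhibitors and related genes (0.0179), glycolysis (0.0202) and smooth muscle (0.0140). Endothelial (0.00451), adipocyte (0.00338), cartilage (0.00312), YAP targets (0.0124) and ubiquitin (0.0366) also gained a fry call. Since 59.1% of all tested genes were called, these gains do not set the lists apart from other genes. Leaving out each library gave adjusted p ranges by camera of 1.14e-05 to 0.352 for leukocyte, 0.0204 to 0.0522 for erythroid, 0.00418 to 0.0502 for neural, 0.00754 to 0.0599 for epithelial and 0.0192 to 0.0589 for cell death lists, and other list calls did not change. Of the 9436 calls it lost between 417 (myoblast replicate 3) and 1667 (myotube replicate 2), with 1 change of sign. Members called fell to 3 epithelial markers under limma on FPKM, TPM, median-ratio and quantile scaling, and to 22 ribosomal genes under quantile normalization. Of 2193 alternative values for the 157 named genes, 2150 kept direction and call, 34 lost and 7 gained a call, and 2 reversed: MT-ND3 to -0.011 under quantile normalization and MYOG to 0.14 without myoblast replicate 3 (-0.40 to 0.14 over the libraries left out). The share of summed FPKM in the 10 highest genes, -1.15 percentage points, reversed to 0.067 without mitochondrially encoded genes and 0.49 without the 10 highest, that of the 50 highest moved from 1.47 to 3.35 and 3.30, of the 100 highest from 3.95 to 5.76 and 5.55, and the fibroblast share reversed from 0.027 to -0.028 (up to 0.056) when libraries were left out. Of genes simulated with a 2-fold change, 56% were called at or below 26.0 CPM and 94% above it; the lower genes also had the wider dispersion (0.0243 against 0.00951), so depth alone was not tested.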

Other observations

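Of the tests on the patterns described here, those on exchanged labels, on 1 library, on the share of muscle cells, on muscle genes in myoblasts, on scaling and on the endoplasmic reticulum arms were chosen after the result was seen, as were the symbol families; the tests on gene length, on the synthetases and on other splits were not.

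Groups of genes that share a symbol stem were tested beyond the fixed lists, 95 of them, chosen after the values were seen. All 14 nucleoporin genes tested (NUP, the building blocks of the nuclear pore) fell, with a median log2 change of -0.60 (camera, Benjamini-Hochberg adjusted p = 0.00168; adjusted p = 0.925 with an estimated correlation), and 14 fell without myoblast replicate 3. NUP210 and NUP58 changed most, by -1.15 ± 0.13 and -1.09 ± 0.08 (SE, n = 3 libraries each). Of 12 IFT genes, which encode the transport machinery of the cilium, 11 rose and IFT20 had no call at -0.02 ± 0.13, with a median of 0.85 (camera, Benjamini-Hochberg adjusted p = 0.0400; adjusted p = 0.941 with an estimated correlation). IFT81 and IFT122 rose by 1.07 ± 0.15 and 1.00 ± 0.08, and 11 rose without myoblast replicate 3. Of 26 KIF genes, 14 fell, 6 rose and 6 had no call (camera, Benjamini-Hochberg adjusted p = 0.0413, or 0.925 with an estimated correlation). The 8 KIF genes in a fixed list, that of mitosis, all fell, so this call partly repeats the mitosis result. The other KIF genes fell and rose in equal numbers. The 11 PSMD proteasome genes did not pass as a family, with 8 lower (camera, Benjamini-Hochberg adjusted p = 0.0579).

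Among called genes, 3350 had no symbol. The largest rise among those with a mean FPKM of at least 10 was in ENSGALG00000033591 (chromosome 13, 3466335 to 3475168), from 0.0820 ± 0.0573 to 27.5 ± 2.19 FPKM (log2 change 8.36 ± 0.26, n = 3 each), and the largest fall in ENSGALG00000015143 (-5.92 ± 0.33). ENSGALG00000010926 (chromosome 4, 45974555 to 45977750) went from 1139 ± 151 to 44.1 ± 1.68 FPKM. Reads of W chromosome genes, 141 in the tables, summed to 365 to 418 CPM in the 6 libraries.

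In the libraries labelled myotube 30 of 51 sarcomere genes were lower, 2 were higher and 19 had no call. The list was called by camera at its preset correlation, but not with an estimated one (Benjamini-Hochberg adjusted p = 0.622) or by fry (0.0672). The tables argue against exchanged group labels, since the mitosis median was -2.22, and against myoblast replicate 3 as the sole cause, since the sarcomere median was -0.51 without it. A lower share of muscle cells with the same expression per cell would move all members alike only if no other cells expressed them. The 41 members with a mean FPKM of at least 10 had an interquartile range of 1.36 against a median standard error of 0.28. DES was at -2.47 and TNNI1, chosen after its value was seen, at 0.17. Which members other cells of these cultures expressed was not measured, so this spread cannot decide on a lower share of muscle cells. Many sarcomere genes were already active in the cultures labelled myoblast, where 49.0% of the members lay in the top 10% of tested genes by FPKM. Whether this accounts for the lower values in myotubes stays open. The serum or the time of harvest may also have contributed, which was not tested.

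Ribosomal protein genes rose together. Short and abundant genes were also higher, with a median of 0.34 in the middle of 10000 lists matched on length and count (95% of them 0.16 to 0.54). The ribosomal list exceeded that middle by 0.27, with 59 of 10000 lists as high. The matched lists were drawn gene by gene, without the correlation between members, and how closely other genes matched ribosomal ones was not checked. This test therefore cannot decide whether that trend carries part of the rise or the whole. A shift from the normalization cannot be told apart from a change in these genes, because the list's median above that of all genes was 0.18 under quantile normalization, which equalizes the top of the range, and 0.58 to 0.60 under 5 other scalings or fits.

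Within the list of endoplasmic reticulum and integrated stress, 11 genes of the amino acid response had a median of 2.47 and 14 chaperone and related genes one of 0.18, a difference of -2.29 on the log2 scale. The list was divided after the values were seen, so a stress of the endoplasmic reticulum as a whole cannot be told apart from an amino acid response by this difference. An amino acid response that reaches related genes remains open as a hypothesis: the 18 cytosolic aminoacyl-tRNA synthetase genes had a median of 0.37 against -0.14 for count-matched lists, as high in 40 of 10000. Of these 11 rose, led by WARS (1.38 ± 0.09) and GARS (1.32 ± 0.11), both named after their values were seen, and 4 fell, so the response may not cover the whole family.

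The 6 libraries can be split in 10 ways into 3 against 3, too few for a share under 0.05. The real split called 9436 genes and 10173 had an unadjusted p under 0.05; the highest of the other 9 splits called 0 genes by edgeR quasi-likelihood, with 30 to 235 at an unadjusted p under 0.05, so 1 of 10 splits reached the real count. For the lists, 6 of 10 splits called at least the 19 lists of the real one with camera, with 22 the highest of the others. Each of the other 9 splits mixes both states on each side. The difference between the states then stays partly between the sides and also widens the spread within them. Neither the gene counts nor the list counts of these splits therefore show what chance alone would give.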
